A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

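Strand-specific RNA sequencing was done on 14 libraries of Saccharomyces cerevisiae W303, wild type and an rpd3 deletion, harvested as log, DS (diauxic shift) and purified Q (quiescent) cells. Per the labels' protocols, total RNA was depleted of ribosomal RNA, ERCC spike-in transcripts were added, and 2 isolates were prepared per condition; wild-type log cells had 4 libraries, with 0.2 and 1 spike equivalents for each isolate. Per the submitters' processing notes, CASAVA, TopHat2, SAMtools, Cuffdiff and Cufflinks 2.2.1 were used; their settings, the genome build and the annotation are not given in the sources used here. The deposited table holds log2 values of FPKM that the authors normalized with the spike-ins to RNA content per cell, per the series design text and the name of the table. It has 1 value per condition, and how the isolates and the spike amounts were combined is not stated. The log base is not stated either and was read from the values: FPKM times gene length summed to 1295760 in wild-type log cells with base 2, which is near the sum that unscaled FPKM has by construction, and to 31190800 with base e. The design had assumed FPKM on a linear scale or replicate columns, so the form for 1 value per condition, written beside it before the data were examined, was used.

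The table has 6602 named rows. The 4 rows of 2 names used more than once were left out because their values could not be assigned, which left 6598 genes; 1 name had turned into a date and was kept as it stands without a gene assignment. Of these names 5966 matched a gene of the reference annotation and 632 did not. The reference served for names, gene lengths, upstream sequence and the order of genes, and no position is given, since the authors' build is unknown. Blank cells (0, 11, 133, 88, 42 and 146 in wild-type log, DS and Q and mutant log, DS and Q) were taken as no value. In the mutant DS column, 108 values at the end of the table repeat the start of the mutant Q column and were left out; this was decided after the data were seen. List genes with no row used here were TEF1, TEF2, YEF3, FBA1, TDH3, ENO2, CDC19 and PDC1. RPB6 is another name of RPO26, which was used under that name; ATG31 has the older name CIS1 in the table and was left out of its list, which was matched by name.

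Each value was turned back to FPKM, genes with at least 1 FPKM in at least one condition were kept (6524), and a change was the difference of log2(FPKM + 1). The pseudocount of 1 compresses changes of genes near or below 1 FPKM, which in wild-type Q cells is a large part of the table. There were 9 comparisons: Q and DS against log and Q against DS in wild type, mutant against wild type at each of the 3 harvests, Q and DS against log in the mutant, and the difference between genotypes in the change from log to Q. With 1 value per condition no test and no p can be had; genes with a change of at least 2-fold were counted and the median change was given. Total counts per library are unknown, so no interval or detection limit could be given.

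The lists of genes, fixed before the data were examined, were ribosomal proteins, ribosome biogenesis, translation factors, RNA polymerase subunits, glycolysis and fermentation, gluconeogenesis and glyoxylate cycle, TCA cycle, oxidative phosphorylation, peroxisomal beta-oxidation, trehalose and glycogen, stress and heat shock, stationary phase genes, histones, cell cycle G1/S, cell cycle G2/M and M/G1, proteasome, autophagy, hexose transporters, amino acid biosynthesis, meiosis and sporulation, Rpd3-repressed genes of the literature, Rpd3 complexes and recruiters, a-specific, alpha-specific and haploid-specific genes, and retrotransposon and subtelomeric families. The last of these lists was matched by the names YRF1, COS and PAU only, so it holds subtelomeric genes and no retrotransposons. For each of the 26 lists the median change was set against 10000 random lists of the same size. These were matched in 10 bins on mean expression over all 6 conditions (seed 20). A list was called outside the random range at or below the percentile of 2.5 or at or above 97.5. Chance would put 1.3 of 26 lists outside per comparison, or 11.7 of 234 in all, and 136 were outside. Members of a list are not independent of each other, which this count does not allow for.

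Genes were named by a rule fixed before the data were examined. It took per comparison the 12 largest increases and the 12 largest decreases among genes at or above the table's 25th percentile (7.38 FPKM) in at least one condition compared, without systematic names unless among the 3 largest; the text names most of these. It added the 2 to 4 members with the largest change of each list that had a median of at least 2-fold or lay outside the random range, and members against the list, of which the text names examples. RPD3 and the Rpd3-repressed list were named in every comparison of genotypes. XBP1, STB3, the genes of the opposite-direction results and the mitochondrial genes outside this rule were picked by interest.

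The calculation was tested on simulated data: fold changes were put into 200 of 6143 genes. All simulated conditions were built from wild-type log values with a log2 of at least 2. The recovery given next therefore does not cover the low values of wild-type Q cells. It also rests on added noise of an assumed size, since the spread between isolates is unknown. In each of the 8 comparisons of a pair of conditions, 95.5% to 99% of genes with a simulated 3-fold change and 100% with an 8-fold change were recovered, and the difference between genotypes in the change from log to Q was not simulated. For wild-type Q against log cells, 5.5% of 200 random lists lay outside the range, and 100% of lists shifted by 2 log2 units were found. Smaller shifts and other comparisons were not tried for lists. Promoters were the 500 bases upstream of 5890 genes. Alternatives tried were pseudocounts of 0.1 and 10, no filter and a filter at 10 FPKM, columns centred on their median gene, a threshold of 4-fold, and lists without members shared with another list; no pseudocount, blanks as 0 and keeping the repeated stretch were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.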

Results

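RNA was measured in wild-type budding yeast and in a strain lacking RPD3, the gene of a histone deacetylase, at 3 harvests on the way into quiescence. Log cells were growing on glucose, at an OD600 between 0.4 and 0.6; DS cells (diauxic shift) were harvested 2 hours after the glucose had run out, and Q cells were the dense quiescent fraction purified on Percoll from 7-day cultures. The 14 libraries were strand-specific, depleted of ribosomal RNA and carried ERCC spike-in transcripts. Each of the 6 conditions had 2 isolates, and wild-type log had 4 libraries because each of its isolates was prepared with 0.2 and with 1 spike equivalents. The deposited table holds 1 value per condition, so there are no replicates, no SD and no test behind any value here, and the read depth is unknown. "Higher" and "lower" below therefore describe single pooled values. Values are FPKM normalized by the authors to RNA content per cell, and a change is the difference of log2(FPKM + 1) between conditions.

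Wild-type quiescent cells held far less RNA of the genes in the table per cell than growing cells on this scale. The median gene had 38.0 FPKM in wild-type log cells, 20.1 in DS cells and 1.37 in Q cells, and 42.1% of genes with a value were below 1 FPKM in wild-type Q cells. The sum of FPKM times gene length in wild-type DS cells was 47.2% of the wild-type log sum, and in wild-type Q cells it was 5.86%. In the mutant the medians were 50.2, 33.9 and 19.0 FPKM, and the sums were 108.8%, 65.3% and 27.3% of the wild-type log sum. The mutant to wild-type ratio of these sums was 1.09 in log, 1.38 in DS and 4.66 in Q. Each sum covered the genes matched to the reference with a value in that condition, without the repeated stretch of mutant DS. The ratios are therefore not over exactly the same genes. Over the genes with a value in all 6 conditions, FPKM not weighted by length summed to 1343660 in wild-type log cells. The same sum was 53866 in wild-type Q and 300539 in mutant Q cells. Because the scale itself shifts most genes, the median of all genes is given for each comparison, and lists of genes are read against it. Where the direction of a list turned when every column was centred on its median gene, the centred value stands beside it. Centring rescaled the columns before the pseudocount of 1 was added, so the pseudocount weighs less on centred than on deposited wild-type Q values. Centred values can therefore differ from deposited ones by more than the common shift.

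**Figure D1:**
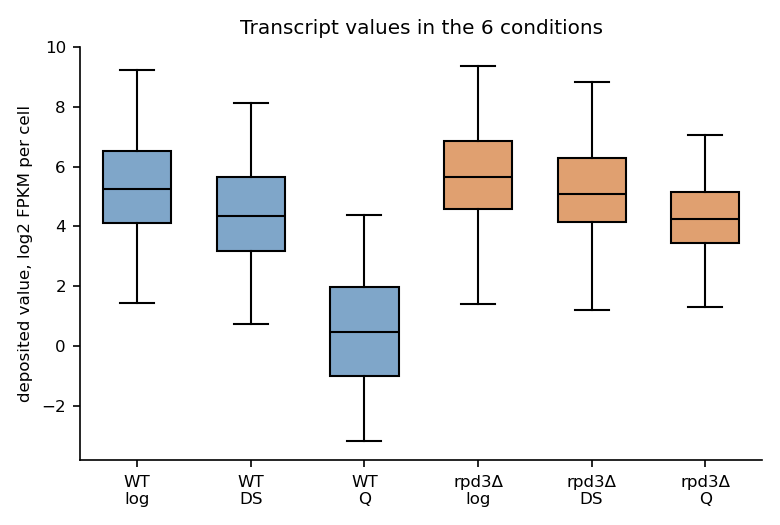
Deposited values of all genes in the 6 conditions, in log2 FPKM per cell; boxes span the quartiles, the line is the median and whiskers reach the 5th and 95th percentiles. The wild-type Q median of 1.37 FPKM lies below the mutant Q median of 19.0 FPKM.

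The comparison of wild-type DS with log cells asks what follows glucose exhaustion. Genes for growth on ethanol and acetate were higher in DS cells, and genes of the ribosome were lower. PCK1, whose product catalyses the committed step of gluconeogenesis, was at 5.62 FPKM in log and 4142 in DS cells (log2 change 9.29). All 136 ribosomal protein genes were at least 2-fold lower, with a median of -4.86. Among 6519 genes, 646 were at least 2-fold higher and 2881 at least 2-fold lower, and the median change was -0.85 (-0.55 with a pseudocount of 10); with centred columns the counts were 1317 and 1439.

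All 20 genes of gluconeogenesis and the glyoxylate cycle were at least 2-fold higher in DS cells, with a median of 5.91. They included MLS1, malate synthase (9.27), FBP1, fructose-1,6-bisphosphatase (8.24), and SFC1, the mitochondrial succinate-fumarate carrier (8.12). Of the 16 TCA cycle genes 15 were at least 2-fold higher (median 2.71), led by the succinate dehydrogenase subunit SDH2 (4.22) and aconitase ACO1 (3.82). For nuclear genes of oxidative phosphorylation the count was 26 of 30 (median 1.66), with QCR10 of complex III at 2.89 and the NADH dehydrogenase NDI1 at 2.81. Peroxisomal beta-oxidation had 12 of 14 genes higher (median 2.43), including the thiolase POT1 (4.32) and the multifunctional enzyme FOX2 (3.71).

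The stress and heat shock list had 24 of 25 genes at least 2-fold higher and a median of 3.81. Its largest changes were in SIP18, a hydrophilin linked to desiccation (9.90), the small heat shock chaperone HSP26 (9.71), the membrane-stabilising HSP12 (8.62) and DDR2 (7.99). GRE1, another hydrophilin, changed by 7.88, RGI2, a gene of respiratory growth, by 7.80, and YLR307C-A, of unknown function, by 10.06. Stationary phase genes had 10 of 14 members at least 2-fold higher, among them SPG4 (8.25), SPG1 (7.45) and the protease inhibitor gene PAI3 (6.15), while the stress transcription factor MSN4 was lower (-1.19). Trehalose and glycogen genes had a median of 1.83, with the glycogen debranching enzyme GDB1 at 3.40 and the trehalase ATH1 at 3.33; UGP1, which makes UDP-glucose, went the other way (-1.02). Autophagy genes had a median of 0.56 with 7 of 19 at least 2-fold higher, led by ATG8 (2.16) and the vacuolar protease PRB1 (1.43).

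Ribosome biogenesis had all 43 genes at least 2-fold lower (median -4.19), with the nucleolar proteins NSR1 at -6.40 and NOP1 at -5.72. Of 25 translation factors 24 were at least 2-fold lower (median -3.09), and of 31 RNA polymerase subunits 30 (median -3.08), led by RPA49 of RNA polymerase I (-5.22). The largest decreases of single genes were in HXT2, a high-affinity glucose transporter (-7.29), DBP2, an RNA helicase (-6.91), YLR413W (-6.78) and UTR2, a cell wall transglycosylase (-6.72). Next came RPL9A (-6.57), ASC1 of the small ribosomal subunit (-6.41), IMD4, an IMP dehydrogenase (-6.23), URA7, a CTP synthase (-6.19), RPS22A (-6.15) and RPS26B (-6.06). BUD28 (-6.06) overlaps RPL22A, so its value is uncertain, as are those of near-identical ribosomal protein pairs. G1/S cell cycle genes had 23 of 25 members at least 2-fold lower (median -1.88), including the ribonucleotide reductase gene RNR1 (-3.75), and the a-specific genes had 5 of 7 (median -2.55), including the receptor gene STE2 (-3.93). Of the 26 lists 14 lay outside the 95% range of random lists matched on expression, against 1.3 by chance.

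The change from wild-type log to Q cells addresses what the quiescent cell keeps. Almost every transcript was lower per cell in Q than in log cells, while a small set of stationary phase and stress genes was higher. SPG1, needed for survival of heat in stationary phase, was at 3.57 FPKM in log and 1487 in Q cells, and RPS22A of the small ribosomal subunit was at 4912 and 2.02. Among 6425 genes, 118 were at least 2-fold higher and 5990 at least 2-fold lower, and the median change was -3.87 (-1.98 with a pseudocount of 10). With centred columns the counts were 1911 and 2103. Taken relative to the median change, without rescaling the columns, they were 1734 and 1778. The split between higher and lower genes thus depends on the per-cell scale.

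The largest increases in Q cells were in SPG1 (8.35), SPG4 (7.62), GRE1 (7.45) and SIP18 (7.37). They were followed by RGI2 (6.61), the acetate transporter gene ADY2 (6.02), HSP26 (5.81), SPS100, a spore wall gene (4.71), and HXT5, a hexose transporter of slow-growing cells (4.10). NQM1, a transaldolase paralog (3.78), NDE2, a mitochondrial NADH dehydrogenase (3.66), and HBT1 (3.53) completed the 12. The largest decreases were in BUD28 (-10.81), RPS22A (-10.67), the plasma membrane proton pump PMA1 (-10.30), RPP2A of the ribosomal stalk (-10.04) and the flavohemoglobin YHB1 (-10.03). The cell wall mannoprotein gene CCW12 (-10.02), the S-adenosylhomocysteine hydrolase gene SAH1 (-10.01), RPL9A (-9.92), RPP2B (-9.87), the HSP70 gene SSA2 (-9.83) and RPS11B (-9.80) were next.

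Ribosomal protein genes were lowest as a group: all 133 were at least 2-fold lower, with a median of -8.32, which is -4.46 relative to the median gene. Ribosome biogenesis had all 43 genes lower (median -6.25), including NOP58 (-8.10) and NOP56 (-7.92), and RNA polymerase subunits had all 31 lower (median -5.48), including RPO26 (-7.69). Translation factors (-6.39, percentile 11.4 among random lists), glycolysis and fermentation (-6.62, 17.2), amino acid biosynthesis (-6.08, 14.3), histones (-5.13, 74.9) and the proteasome (-5.13, 59.8) were also lower but lay inside the random range. Examples were the elongation factor TEF4 (-9.36), hexokinase HXK2 (-9.24), asparagine synthetase ASN1 (-8.97), the H2B gene HTB2 (-8.13) and PRE6 (-6.45). G1/S genes (median -4.62), G2/M and M/G1 genes (-4.78) and a-specific genes (-6.45) lay below the random range, with RNR1 at -7.55, the daughter-cell gene DSE2 at -8.01 and the a-factor gene MFA2 at -8.75. Haploid-specific genes had a median of -4.97, with the G protein gene GPA1 at -5.64. With a pseudocount of 10 the G1/S and the G2/M and M/G1 lists moved inside the range, to percentiles 12.3 and 9.97.

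Several lists stayed closer to their log level than the median gene did. Some of their members were low in log cells and had little room to fall. With a pseudocount of 1, SFC1 (1.88 FPKM in log cells) and PCK1 (5.62) could not reach the median change of -3.87. The random lists were not matched on the log level. Stress and heat shock genes had a median of -0.07 (4.71 with centred columns) with 9 of 25 at least 2-fold higher and 11 at least 2-fold lower; DDR2 (3.51) and HSP12 (3.22) were among the higher. Stationary phase genes had a median of 0.69, with MSN4 (-5.39) and the kinase gene RIM15 (-3.49) lower. Gluconeogenesis and glyoxylate genes had a median of -0.28 (4.22 centred), with ADY2, the acetyl-CoA synthetase gene ACS1 (3.29) and the lactate transporter gene JEN1 (7.87 to 70.2 FPKM) higher and the peroxisomal citrate synthase gene CIT2 lower (-2.99). Beta-oxidation genes had a median of 0.24, with POT1 at 3.04 and the transporter gene ANT1 at -5.50. Autophagy genes (-1.72, 2.54 centred) held ATG8, the only member at least 2-fold higher (1.35). Trehalose and glycogen genes (-2.44, 2.27 centred) had UGP1 lowest (-6.20).

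TCA cycle genes (-3.99, 0.63 centred) and oxidative phosphorylation genes (-4.12, 0.44 centred) were slightly below the median of all genes (-3.87). Both lists lay above random lists matched on mean expression over all 6 conditions, which does not match them on their log level. The cytochrome c gene CYC1 was at -7.73 and LSC1 at -5.93. Genes described as repressed by Rpd3 had a median of -2.19 (1.42 centred; percentile 99.2), with the phosphatase gene PHO5 at -6.97. Further lists lay inside the random range and turned sign with centred columns: hexose transporters (-4.54 and 0.19), meiosis and sporulation (-2.06 and 1.42), Rpd3 complexes and recruiters (-3.30 and 0.96) and alpha-specific genes (-1.54 and 1.54). Subtelomeric families (YRF1, COS and PAU genes), whose near-identical copies make their values uncertain, had a median of -3.02 (0.06 centred). HXT5 went against the hexose transporters, of which HXT3 was lowest (-9.27). With centred columns the TCA cycle (percentile 85.6), oxidative phosphorylation (88.5) and Rpd3-repressed genes (95.9) moved inside the range. In all 15 of 26 lists lay outside the random range.

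**Figure D2:**
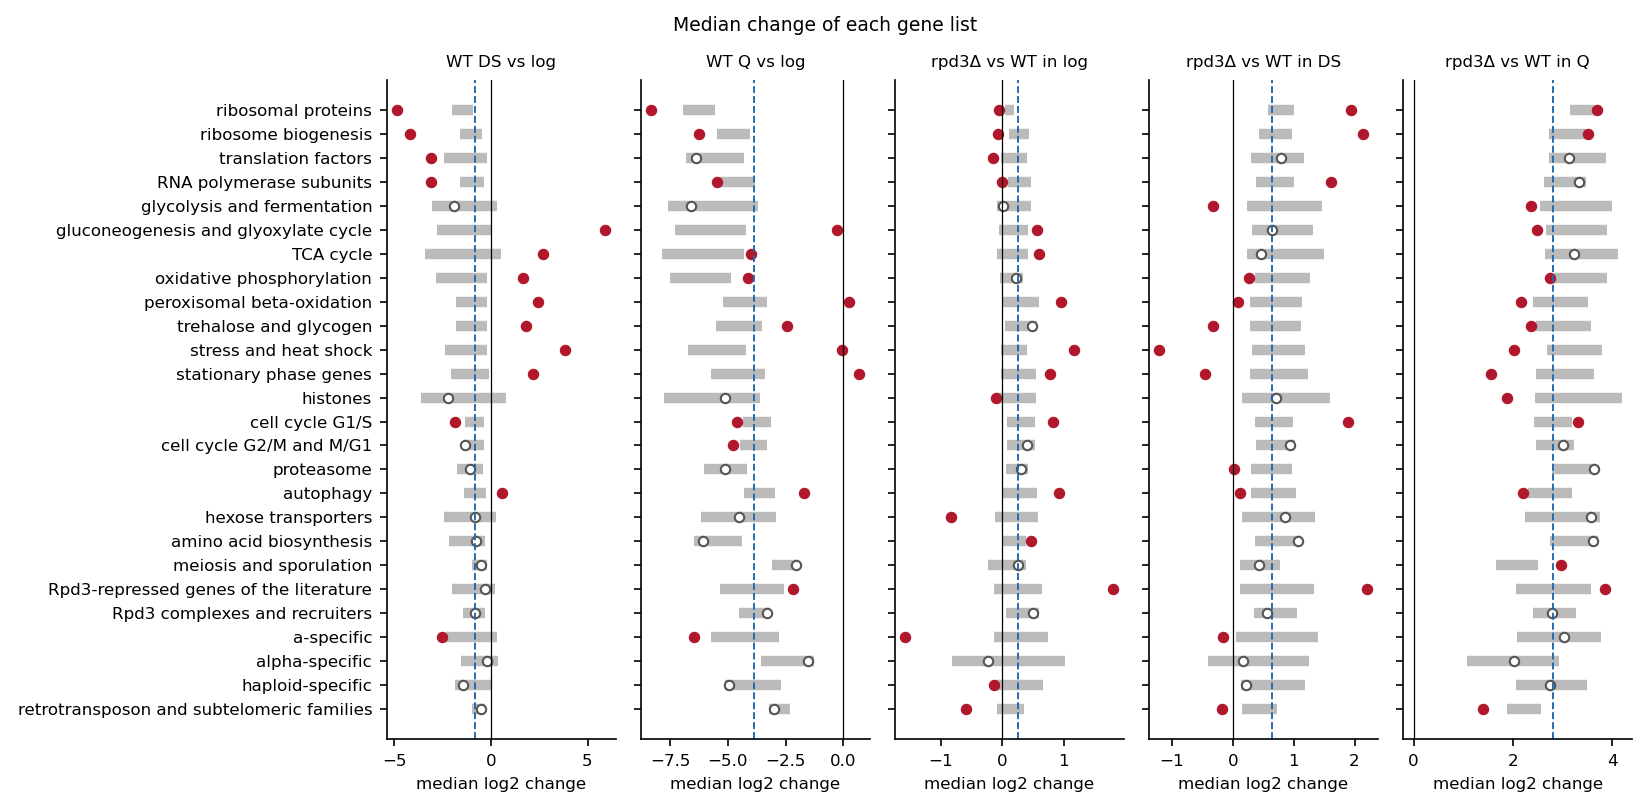
Median log2 change of each of the 26 gene lists (points, filled where outside the random range), the 95% range of random lists matched on expression (grey bars), and the median of all genes (dashed line) in 5 comparisons. The list labelled retrotransposon and subtelomeric families holds no retrotransposons. In Q cells ribosomal proteins stood at -8.32 and stress genes at -0.07 (4.71 with centred columns) against log in wild type; stress genes stood at 2.02 (-1.74 centred) in mutant against wild-type Q cells.

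Between wild-type DS and Q cells the metabolic genes induced in DS cells were lower again, as were most other genes. FBP1 was at 2880.3 FPKM in DS and 3.04 in Q cells (log2 change -9.48), and MLS1 (-8.48), PCK1 (-8.44) and the isocitrate lyase gene ICL1 (-8.40) changed in the same way. All 20 gluconeogenesis genes (median -5.41), all 16 TCA cycle genes (-6.24) and all 30 oxidative phosphorylation genes (-5.79) were at least 2-fold lower. So were all 33 amino acid biosynthesis genes (-5.23), a list that was not higher in DS than in log cells (median -0.79). YHB1 (-9.27), the membrane stress gene HSP30 (-9.24), CYC1 (-9.12), MRH1 (-9.02), the ATP synthase gene ATP2 (-8.86), CWP2 (-8.39) and TIP1 (-8.34) of the cell wall and ACH1 (-8.31) were also among the lowest. Of 6420 genes, 11 were at least 2-fold higher and 6076 at least 2-fold lower, with a median of -2.90 (-1.31 and 2 higher genes with a pseudocount of 10, 17 higher genes with 0.1); with centred columns the counts were 1575 and 1630.

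Among the transcripts named by the rule as highest in Q against DS cells were HXT2 (2.12), SPG1 (0.90), the repair gene RAD16 (1.01), ALT2 (0.94), MIH1, a mitotic phosphatase gene (0.87), IRC2 (1.18), AI5_ALPHA (0.72), DIA3 (0.65) and the mitochondrial Q0143 (2.19), ATP8 (1.94), AI5_BETA (1.25) and RPM1 (0.95). Of these only Q0143, HXT2, ATP8, AI5_BETA, IRC2 and RAD16 reached 2-fold, and the others of the 11 genes that did have systematic names. Ribosomal proteins (-3.35, 0.28 centred), ribosome biogenesis (-1.94, 1.33 centred), RNA polymerase subunits (-2.64, 0.71) and translation factors (-3.26, 0.39) lay above random lists matched on mean expression. Beta-oxidation (-1.77, 2.01), stationary phase (-2.62, 1.19), histone (-2.84, 0.97) and autophagy genes (-2.23, 1.41) did so too, as did the Rpd3-repressed genes (-2.15, 0.10); the value after each median is the centred one. Several of these moved inside the range under an alternative: translation factors (percentile 84.8), RNA polymerase subunits (95.7) and histones (95.3) with centred columns, and beta-oxidation (95.4), stationary phase (94.8), histone (97.2) and autophagy genes (76.9) with a pseudocount of 10. Stationary phase genes did so without shared members too (92.6), and the Rpd3-repressed genes with centred columns (51.5), with either pseudocount (69.3 with 0.1) and without shared members (68.3). Stress genes (median -3.91), including YGP1 (-8.13), and trehalose and glycogen genes (-3.81), including GSY2 (-6.49), were lower within the random range. The random lists were matched on mean expression over all 6 conditions, not on the DS level from which this change starts. Ribosome biogenesis genes had already changed by a median of -4.19 from log to DS cells. With a pseudocount of 1, a gene such as NSR1, at 3.82 FPKM in DS cells, could fall little further. A position above random lists therefore does not show that lists already low in DS cells were spared in Q cells.

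The comparison of genotypes in log cells asks which transcripts depend on Rpd3 during growth. RPD3 itself was at 70.8 FPKM in wild type and had no value in the mutant. Genes known to be repressed by Rpd3 were higher in the mutant: 7 of 9 were at least 2-fold higher and the median was 1.81. INO1, the inositol-3-phosphate synthase gene, was at 12.6 FPKM in wild type and 149.7 in the mutant (3.47), and the arginine catabolic genes CAR1 (2.08) and CAR2 (2.07), PHO5 (1.85) and the potassium transporter gene TRK2 (1.22) were also higher. The meiotic genes of that list were at 1.81 (HOP1), 1.59 (SPO11), 0.99 (IME2) and 0.67 (SPO13). Of 6479 genes, 658 were at least 2-fold higher and 219 at least 2-fold lower, with a median of 0.25; the counts were 265 and 381 with centred columns and 313 and 80 with a pseudocount of 10.

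The largest increases in mutant log cells were in MND1, a meiotic recombination gene (3.67), INO1, YJR005C-A (3.32), FMP23 (3.22), SHC1, a sporulation gene of chitin synthesis (3.06), the meiotic gene ECM11 (2.94), and GAT4 of the spore wall (2.88). HSP26 (2.83), UGX2 (2.79), the meiotic gene HED1 (2.66), RNP1 (2.66) and UGA2, of GABA degradation (2.63), followed. Stress genes had 15 of 25 members at least 2-fold higher (median 1.16), including SSA4 (2.00) and PRX1 (1.83), and SPI1 against them (-1.31). Autophagy (8 of 19, median 0.93), with ATG7 at 1.58, beta-oxidation (7 of 14, 0.96), with FOX2 at 1.67, and G1/S genes (8 of 25, 0.82), with TOS4 at 1.59, were higher. Stationary phase (0.79), gluconeogenesis (0.57), TCA cycle (0.60) and amino acid genes (0.47) lay above the random range, led by SPG5 (1.87), CRC1 (2.62), LSC2 (1.74) and ARG1 (1.80); with a pseudocount of 10 gluconeogenesis moved inside it (percentile 95.1). In the meiosis and sporulation list 8 of 25 genes were at least 2-fold higher and 7 at least 2-fold lower.

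The largest decreases in mutant log cells were in RPI1 (-4.24), YDR119W-A (-3.84), IMD2 (-3.58), BNA1, of NAD synthesis (-3.39), the a-factor gene MFA1 (-3.31), the pyruvate kinase gene PYK2 (-2.98), ADH7 (-2.92), IMD1 (-2.90) and COS5 (-2.90). The metallothionein gene CUP1-2 (-3.17) and the RNAs RUF5-1 (-3.71) and RUF5-2 (-3.70) of the same repeat were lower too, and their repeated copies make these values uncertain, as for IMD1 and IMD2. The a-specific genes had 5 of 7 members at least 2-fold lower (median -1.58), including MFA2 (-2.64) and the protease gene BAR1 (-2.10). Hexose transporters had 5 of 10 lower (median -0.83), with HXT7 at -2.11 and HXT4 at -1.37. In the subtelomeric families 11 of 38 genes were lower (median -0.59), with COS7 at -2.86. Ribosomal proteins (-0.05), ribosome biogenesis (-0.07) and translation factors (-0.15) were near their wild-type level, with no member at least 2-fold different, and lay below the random range, as did RNA polymerase subunits (0.01, -0.38 centred), histones (-0.11) and haploid-specific genes (-0.14). XBP1 (0.84) and STB3 (0.43), whose products recruit Rpd3, were within 2-fold.

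In DS cells RPD3 was at 37.7 FPKM in wild type and 0.941 in the mutant (-4.32). Ribosome genes kept higher levels in the mutant: all 136 ribosomal protein genes were at least 2-fold higher (median 1.94), as were 41 of 42 ribosome biogenesis genes (median 2.13). Stress genes were lower, with 18 of 25 at least 2-fold lower (median -1.21). Of the 9 Rpd3-repressed genes 8 were at least 2-fold higher (median 2.21), with INO1 at 53.3 FPKM in wild type and 1970.0 in the mutant (5.18). Of 6393 genes, 2003 were at least 2-fold higher and 231 at least 2-fold lower, with a median of 0.64; the counts were 710 and 599 with centred columns and 1058 and 140 with a pseudocount of 10.

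The largest increases in DS cells were in INO1, SRT1 (4.13), the meiotic genes SPO16 (3.95) and IME2, a meiotic kinase gene (3.73), GFD2 (3.62), URA7 (3.58) and MND1 (3.40). IMD4 (3.29), the tRNA methylation gene TRM11 (3.24), the nucleolar gene NOP13 (3.17), UTR2 (3.16) and PIS1, phosphatidylinositol synthase (3.09), followed. Other genes of the Rpd3-repressed list were CAR1 (2.74), SPO11 (2.29), PHO5 (2.21), HOP1 (2.00), SPO13 (1.90), TRK2 (1.51) and CAR2 (0.88). RNA polymerase subunits had 24 of 31 genes at least 2-fold higher (median 1.61), including RPA135 (2.15), and G1/S genes 23 of 25 (median 1.89), including TOS4 (3.03) and CDC45 (2.48). Examples of ribosome genes were RPS28B (3.04), HAS1 (2.85) and NSR1 (2.82). Amino acid biosynthesis genes (median 1.06) included LEU9 (2.29).

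The largest decreases in DS cells were in YCL048W-A (-6.01), GRE1 (-5.21), BNA1 (-4.72), COS8 (-4.36), RPD3, the chaperone paralogs HSP33 (-4.04), HSP32 (-4.00) and HSP31 (-3.53), whose similarity makes the values uncertain, SPS100 (-3.65), NQM1 (-3.49), FMP45 (-3.42) and SNZ3 (-3.35). Further stress genes were YGP1 (-3.12), DDR2 (-3.01) and HSP26 (-2.98). Stationary phase genes had a median of -0.45, with SPG1 at -2.74 and with SNZ1 (1.94) and SNO1 (1.82) of vitamin B6 synthesis against them. Glycolysis (-0.33), trehalose and glycogen (-0.32), a-specific (-0.16) and subtelomeric genes (-0.18) lay below the random range, with PYK2 at -2.86, TPS2 at -0.67, MFA1 at -1.24 and COS7 at -3.17; HXK2 (2.37), PDC5 (1.41) and GLG2 (1.22) went against them. The proteasome (0.02, -0.71 centred), oxidative phosphorylation (0.26, -0.47), beta-oxidation (0.08, -0.65) and autophagy (0.12, -0.58) also lay below it, and they turned sign with centred columns, where oxidative phosphorylation moved inside the range (percentile 6.48). XBP1 (0.01) and STB3 (0.34) were within 2-fold.

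In Q cells RPD3 was at 2.35 FPKM in wild type and 0.0279 in the mutant (-1.70), while nearly every other transcript was higher in the mutant. Of 6419 genes, 6069 were at least 2-fold higher and 22 at least 2-fold lower, with a median of 2.81. The median was 1.25 with a pseudocount of 10, with 8 lower genes, and 3.71 without one; with centred columns the counts were 1436 and 1734. All 9 Rpd3-repressed genes were at least 2-fold higher (median 3.85), with INO1 at 5.80, CAR1 at 5.46, HOP1 at 3.95, CAR2 at 3.85, PHO5 at 3.77, SPO13 at 3.18, SPO11 at 2.94 and TRK2 at 2.85, and with IME2 at 0.852 FPKM in wild type and 28.7 in the mutant. Ribosomal proteins had 132 of 133 genes at least 2-fold higher, with a median of 3.70, 0.88 above the median gene (0.13 with centred columns). RPS22A was at 2.02 FPKM in wild type and 147 in the mutant.

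The largest differences in Q cells were in HOR2, a glycerol-3-phosphatase gene (6.98), the retrotransposon frames YBL005W-A (6.79) and YMR046C (6.79), GDH1, glutamate dehydrogenase (6.61), TUB2, beta-tubulin (6.59), TIP1 (6.42), PFY1, profilin (6.31), and TPM1, tropomyosin (6.22). SIT1, a siderophore transporter gene (6.21), HXT6 (6.15), SAH1 (6.09) and the amino acid permease gene AGP1 (6.06) followed; the retrotransposon copies, HXT6 and HOR2 have close paralogs, so their values are uncertain. Genes lower in the mutant were ALD3 (-2.46), GRE1 (-2.03), BNA2 (-1.84), SIP18 (-1.60), HBT1 (-1.36), the catalase gene CTT1 (-1.23) and the mitochondrial ATP8 (-2.74), Q0143 (-2.13), RPM1 (-1.28), AI3 (-1.27), AI5_ALPHA (-1.25) and AI5_BETA (-0.84).

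5 lists lay above random lists in mutant Q cells: ribosomal proteins, ribosome biogenesis (median 3.52), G1/S genes (3.31), meiosis and sporulation (2.97) and the Rpd3-repressed genes. With a pseudocount of 10 ribosome biogenesis (percentile 86.3), G1/S (23.4) and Rpd3-repressed genes (96.7) moved inside the range, with centred columns meiosis and sporulation (87.8), and without shared members the Rpd3-repressed genes (86.1). The lists above included YTM1 (4.77), the cyclin gene CLN3 (4.43), ZIP1 of the synaptonemal complex (4.13) and the meiotic recombinase gene DMC1 (3.94). 10 lists lay below the random range although most of their members were higher in the mutant, and with centred columns they were lower: stress (2.02, -1.74 centred), stationary phase (1.57, -2.22), histones (1.89, -1.71), beta-oxidation (2.17, -1.44), autophagy (2.21, -1.24), trehalose and glycogen (2.36, -1.32), glycolysis (2.37, -1.39), gluconeogenesis (2.48, -1.24), oxidative phosphorylation (2.75, -0.88) and the subtelomeric families (1.39, -0.86). Of these, gluconeogenesis (percentiles 5.29 and 27.7), oxidative phosphorylation (18.9 and 7.74) and trehalose and glycogen (2.77 and 43.1) moved inside the range both with centred columns and with a pseudocount of 10, and beta-oxidation (91.6) and autophagy (48.6) with the pseudocount alone. Members with the largest differences were HSP30 (5.11), STF2 (3.21), HTB2 (3.31), ANT1 (4.19), ATG18 (3.60), UGP1 (4.07), HXK2 (5.41), CAT2 (5.25), ATP2 (4.70) and COS6 (3.53). Hexose transporters (3.57, percentile 92.5), a-specific genes (3.02, 52.9), amino acid biosynthesis (3.62, 93.3) and the proteasome (3.64, 96.3) were inside the range. STB3 (2.81) was at the median of all genes, and XBP1 (1.13) below it.

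**Figure D3:**
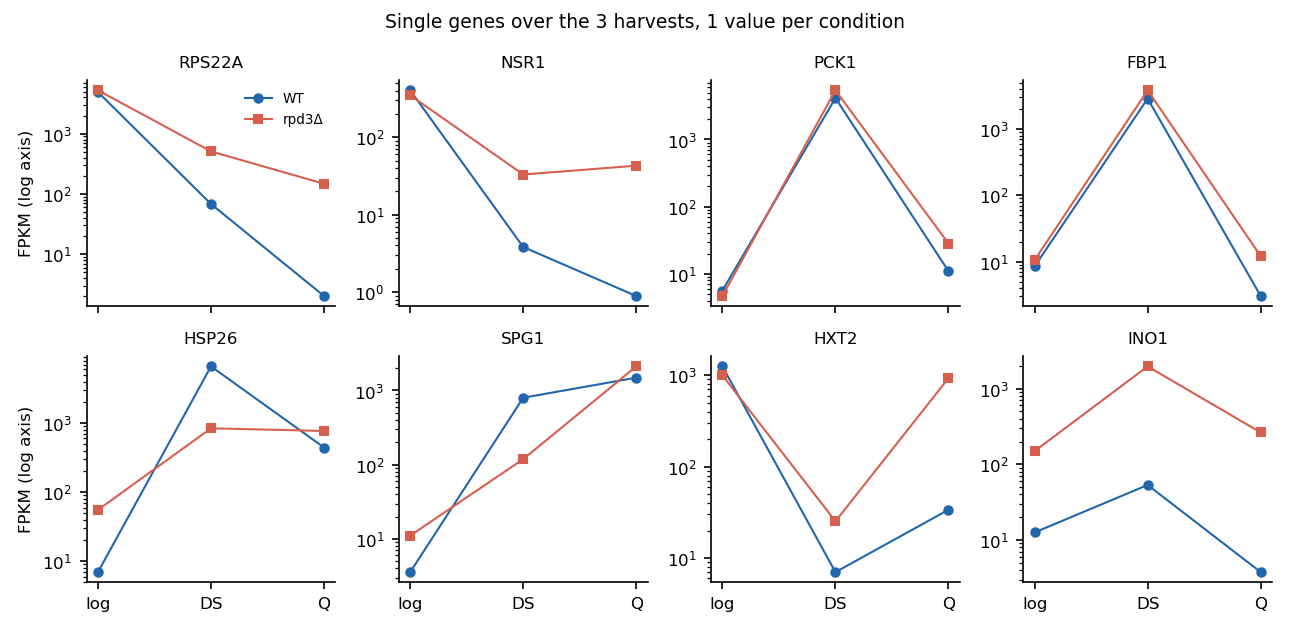
FPKM (log axis) of 8 genes over log, DS and Q cells in wild type (circles) and the mutant (squares), 1 pooled value per condition. INO1 was higher in the mutant at each harvest, and RPS22A was at 2.02 FPKM in wild-type Q and 147 in mutant Q cells.

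Within the mutant, the median gene differed less between harvests than in wild type. In Q against log cells SPG4 (8.89), RGI2 (7.93), SPG1 (7.45), ADY2 (6.62), SPS100 (5.90), the citrate synthase gene CIT3 (5.81), JEN1 (5.65), DDR2 (5.55), POT1 (5.52), FMP43 (5.22), HXT5 (5.06) and DIA3 (4.94) were highest. YHB1 (-6.69), UTR2 (-6.54), PMA1 (-6.48), the ergosterol genes ERG3 (-6.46) and ERG25 (-6.15), RPL9A (-6.15), the transketolase gene TKL1 (-5.92), IRC7 (-5.86) and the drug pump gene PDR5 (-5.85) were lowest. Of 6396 genes, 279 were at least 2-fold higher and 4153 at least 2-fold lower (median -1.39; 1074 and 1208 with centred columns, and 181 higher with a pseudocount of 10). All 134 ribosomal protein genes were at least 2-fold lower (median -4.61), as were 13 of 15 glycolysis genes (-4.49), with PYK2 against them (2.72). Gluconeogenesis had 14 of 20 genes at least 2-fold higher (median 1.73), beta-oxidation 9 of 14 (1.72) and stress genes 12 of 25 (0.60), with the superoxide dismutase gene SOD2 against them (-2.46). Meiosis and sporulation genes (median 0.21) included IME1, the meiotic master regulator (4.09), and DMC1 (2.33).

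In mutant DS against log cells YLR307C-A (10.73), PCK1 (9.90), MLS1 (9.02), FBP1 (8.38), ICL1 (7.41), RGI2 (7.35), JEN1 (7.31) and SFC1 (7.28) were highest, followed by the carnitine carrier gene CRC1 (6.76). RHR2 (-5.38), HXT2 (-5.25), the phosphoglycerate mutase gene GPM1 (-4.73), IRC7 (-4.51), RPL9A (-4.42), ASC1 (-4.18) and TYE7, a regulator of glycolytic genes (-3.96), were lowest. All 20 gluconeogenesis genes (median 5.27) were at least 2-fold higher and all 136 ribosomal protein genes (-2.89) at least 2-fold lower, against -4.86 in wild type. Stress genes had a median of 1.51 in the mutant and 3.81 in wild type. Of 6362 genes, 480 were at least 2-fold higher and 1819 at least 2-fold lower (median -0.52; 892 and 835 with centred columns). These counts leave out 108 genes whose mutant DS values repeat values of another column.

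Across genes, the changes of the genotypes were correlated. Pearson's r was 0.837 (Spearman's rho 0.817) for Q against log over 6395 genes and 0.855 (0.826) for DS against log over 6362 genes, with genes not being independent replicates. Of 112 genes at least 2-fold higher in wild-type Q than log cells and 279 in the mutant, 78 were shared, where 4.89 would be shared if the sets were independent. For DS against log 345 of 629 and 480 higher genes were shared (47.5 if independent). Of 5976 and 4152 genes at least 2-fold lower in Q than log cells, 4136 were shared, against 3880 if independent, since most genes were lower in both genotypes. Relative to the median gene, 946 of 1708 and 1185 higher genes (316 if independent) and 1016 of 1777 and 1192 lower genes (331) were shared for Q. For DS against log 1627 of 2832 and 1819 lower genes were shared (810 if independent).

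**Figure D4:**
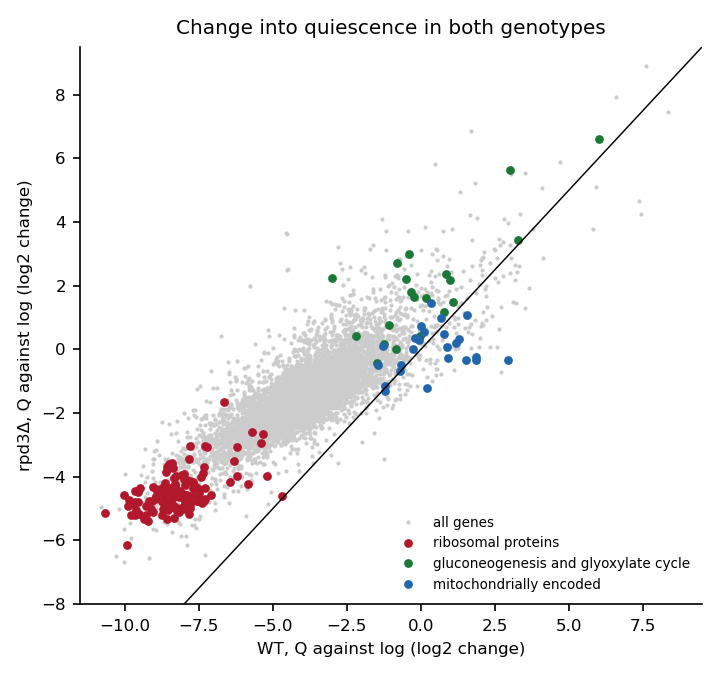
Log2 change from log to Q cells in wild type (horizontal) and the mutant (vertical), each point 1 gene, with equal change on the diagonal and 3 gene groups in colour. Ribosomal proteins had medians of -8.32 in wild type and -4.61 in the mutant, and mitochondrially encoded genes 0.35 and 0.05.

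The difference between the genotypes in the change from log to Q asks how far entry into quiescence depends on Rpd3. Its median over 6395 genes was 2.52, meaning that the decrease per cell was smaller in the mutant, with 5860 genes at least 2-fold above 0 and 44 at least 2-fold below (1700 and 1580 with centred columns). With a pseudocount of 10 the median was 0.99 and the counts were 3178 and 22, and without one the median was 3.47. The glucose transporter genes HXT6 (8.21) and HXT7 (8.14) had the largest positive values, followed by CUP1-2 (7.74), TIP1 (7.17), RUF5-2 (7.02) and RUF5-1 (7.01). MFA2 (6.48), the glycerol-3-phosphate dehydrogenase gene GPD2 (6.40), UTH1 (6.33), MFA1 (6.33), TUB2 (6.18) and SAH1 (6.10) were next. ALD3 (-3.43), Q0143 (-3.26), GRE1 (-3.19), SIP18 (-2.69), UGX2 (-2.47), HBT1 (-2.23), GAT4 (-2.17; its sign turned without a pseudocount), RPM1 (-2.08), HSP26 (-2.03), FMP45 (-1.98), TKL2 (-1.91) and AI5_BETA (-1.86) had the largest negative values.

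5 lists lay above random lists in this difference: ribosomal proteins (median 3.79, 0.57 centred), ribosome biogenesis (3.62, 1.00), RNA polymerase subunits (3.31, 0.42), hexose transporters (4.53, 2.00) and a-specific genes (4.37, 2.03). RNA polymerase subunits moved inside the range with centred columns (percentile 96.7) and with a pseudocount of 0.1 (92.1), and hexose transporters with a pseudocount of 10 (97.4). In Q cells themselves the hexose transporters and a-specific genes lay inside the range, and in log cells both were lower in the mutant (-0.83 and -1.58), which enters this difference. Examples were RPS22A (5.52), NOP56 (4.84), RPO26 (4.59), HXT4 (5.42) and STE6 (5.02). 5 lists lay below the random range and were negative with centred columns: gluconeogenesis (1.47, -1.66 centred), beta-oxidation (1.14, -2.22), stress (0.94, -2.23), stationary phase (0.68, -2.70) and autophagy genes (1.26, -1.61). Among them CIT2 (5.25), HSP30 (6.01) and STF2 (3.60) were well above 0, while HSP12 (-1.76), CTT1 (-1.46) and SNZ1 (-1.33) were below it.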

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

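The tests of the repeated stretch, of a single scaling error, of the mitochondrial transcripts and the second test of a mixture of cells were chosen only after the result was seen; the first test of a mixture was written before.

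A total of 95 genes were at least 2-fold lower in Q than in log cells of wild type and at least 2-fold higher in the mutant, and 0 genes went the reverse way; the difference was not tested, since there is 1 value per condition. The per-cell scale shifts the mutant against wild type in this direction, and with centred columns the counts were 31 and 14. The 95 genes included HXT6 (-4.56 in wild type and 3.65 in the mutant), HXT7 (-4.52 and 3.62), CIT2 (-2.99 and 2.26), CUP1-2 (-5.76 and 1.98), HSP30 (-2.81 and 3.21), PYK2 (-2.72 and 2.72) and the meiotic regulator IME1 (-1.32 and 4.09). For DS against log, 5 genes were lower in wild type and higher in the mutant (BIO5, PRM7, TAH1, YAH1 and YLR162W) and 2 the reverse (PEX22 and SSA4), also untested and named after their values were seen; with centred columns the counts were 2 and 4.

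In the mutant DS column, 108 values at the end of the table equal, in order and to 3 decimals, the values at the start of the mutant Q column. Across these genes the mutant DS value had a correlation of 0.003 with the same genes in wild-type DS cells, against 0.894 for all other genes. The first genes of the mutant Q column, where the values also stand, had 0.778 with wild-type Q and 0.849 with mutant DS. The values therefore go with the genes at the start of the table and not with the genes at its end. This is what a copying error in the table predicts, and no biological explanation was tested. The correlations do not show by themselves that the values are of Q rather than DS cells. Whether the error arose in the table or before it stays open.

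Nearly every gene was higher in mutant than in wild-type Q cells, with a median of 2.81. A single scaling error and a higher RNA content of mutant Q cells cannot be told apart: one factor shifts every gene alike, so the 10 of 26 lists whose difference between genotypes lay outside the random range (9 of them also with centred columns) are no test of it, and spike-in counts per library were not analysed here. Growing or diauxic cells left in the mutant fraction were considered too. Before the result was seen, they predicted that at most 1% of genes would exceed all other conditions by 2-fold. The share was 0.684%, but this prediction could hardly be missed with or without such cells. Only 4.36% of genes were at least 2-fold higher in mutant Q than in mutant log cells, so the share decides nothing. A test chosen afterwards gave 65.4% of the median gene's level. This is what the wild-type Q level and such cells, at the upper quartiles of their lists, supply together. Ribosomal proteins were at 4.05% of their mutant log level (quartiles 3.47% and 5.25%) where 35.1% would be needed, and gluconeogenesis genes, with a wider spread, at 13.4% of their mutant DS level (2.13% and 24.7%) where 51.7% would be needed. The later value is near its bound of 70% and assumes that left-over cells keep the RNA of the log and DS samples. Under that assumption it is a lenient ceiling, because the transcripts with the lowest ratios limit the share of such cells most. The lower quartiles of 3.47% and 2.13% would allow fewer such cells than the upper quartiles used. The value speaks only against these cells as the whole cause. A share of them, non-quiescent stationary cells (not measured) and an effect of the deletion on quiescent cells stay open.

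Mitochondrially encoded transcripts lay above other genes in the change from wild-type log to Q cells: the 25 genes had a median of 0.35, 4.21 above the median gene. Of these 8 were at least 2-fold higher, 4 at least 2-fold lower, and all 25 at least 2-fold above the median gene. One scaling factor moves every transcript alike, so the value of 0.35 is no test of such a factor, and the list was made after its values were seen. In mutant against wild-type Q cells their median was 0.11 (-3.63 with centred columns). How the reads of the mitochondrial genome were filtered is not given in the sources used here, and a slower loss of mitochondrial RNA in quiescent cells stays untested.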

How the results depend on the processing

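No alternative was chosen for its result; no pseudocount, blanks as 0 and keeping the repeated stretch were chosen only after the data were seen. No paired analysis was possible because the table holds 1 value per condition, and for the same reason the planned leave-one-out of isolates, the replicate block, the fit of only the groups compared and the use of only the libraries with 1 spike equivalent could not be run. Comparisons are given in the order wild-type Q against log, DS against log and Q against DS, mutant against wild type in log, DS and Q, mutant Q against log and DS against log, and the difference between genotypes. Of the counts of genes under alternatives 105 stayed within 1.5 times their value and 43 moved; of gene values 1715 stayed, 18 moved and 1 reversed; of list positions 504 stayed, 38 moved into the random range and 2 reversed. Lists were compared by percentile, a choice made after their medians were seen: of 157 list medians of at least 2-fold, 49 changed sign with centred columns and 41 more were under 2-fold. Lists outside the random range numbered 136, against 138 with centred columns, 146 and 135 with pseudocounts of 0.1 and 10, and 131 without shared members.

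With centred columns the genes at least 2-fold higher and lower became 1911 and 2103, 1317 and 1439, 1575 and 1630, 265 and 381, 710 and 599, 1436 and 1734, 1074 and 1208, 892 and 835, and 1700 and 1580. The medians became -0.07, 0.001, 0.016, -0.117, -0.04, -0.087, -0.045, 0.014 and 0.053, since centring takes the common shift out by construction.

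A pseudocount of 0.1 gave medians of -4.70, -0.91, -3.72, 0.68, 3.57, -1.47, -0.54 and 3.33, without log cells of both genotypes, whose median stayed, and 17 genes higher in wild-type Q than DS cells. No pseudocount gave -4.92, -0.91, -3.91, 0.69, 3.71, -1.48, -0.55 and 3.47 for the same comparisons, again 17 genes, and 0.24 for GAT4 in the difference between genotypes, which reversed. A pseudocount of 10 gave medians of -1.98, -0.55, -1.31, 0.20, 0.44, 1.25, -1.02, -0.39 and 0.99, since a larger pseudocount compresses low values by construction. It left 2 genes higher in wild-type Q than DS cells, 313 higher and 80 lower in mutant log cells, 1058 and 140 in mutant DS cells, 8 lower in mutant Q cells, 181 higher in mutant Q than log cells, and 3178 and 22 in the difference between genotypes. In mutant against wild-type Q cells it moved the percentile of beta-oxidation to 91.6 and of G1/S genes to 23.4, across the middle; the cause was not tested. A filter at 10 FPKM gave medians of -4.00, -0.89, -3.00, 0.27, 0.67, 2.89, -1.47, -0.56 and 2.59, by leaving out low genes.

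At 4-fold, 64 genes were higher in wild-type Q than log cells, 308 were higher and 1251 lower in DS than log, and 3 higher in Q than DS. In the mutant 65 were higher and 61 lower in log, 357 and 86 in DS and 4 lower in Q, and 116 were higher and 1830 lower in Q against log, 169 and 460 in DS against log, and 12 below in the difference between genotypes. The depth is unknown, so how much counting error adds to values below 1 FPKM in wild-type Q cells cannot be given.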

Other observations

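The test of chromosome ends was chosen only after the result was seen; the tests of the 4 promoter motifs were written before.

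Mutant Q cells had 43 genes, of 6284, at least 2-fold above each of the other 5 conditions, and wild-type Q cells had 0. These are the 0.684% of genes given for the mixture of cells, and the count of 0 follows in part from the per-cell scale, on which 6069 genes were at least 2-fold lower in wild-type than in mutant Q cells. The 43 included the meiotic genes IME1 (17.6 FPKM in mutant Q cells), DMC1 (48.2), REC8 (11.6) and MEK1 (19.6), the spore wall gene SPS100 (807), the HSP70 gene SSA3 (697) and RNR3, a ribonucleotide reductase gene induced by DNA damage (20.1). These were named after their values were seen.

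Mitochondrially encoded genes, a list made after the data were seen, had a median change of 0.87 from log to DS in wild type and 0.95 in the mutant. In the difference between genotypes in the change from log to Q they had -0.03, -2.56 relative to the median gene.

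A hypothesis was that genes with binding sites of repressors known to recruit Rpd3 are further above wild type in mutant Q cells than other genes. The RRPE element of Stb3 (TGAAAAATTTT, 178 genes) went with a median of 3.52 against 2.83 without it, the PAC element of Dot6 and Tod6 (GCGATGAG, 288 genes) with 3.35 against 2.82, and the Xbp1 core (CTCGAR, 1455 genes) with 3.09 against 2.78, each at percentile 100 of random lists matched on expression. RRPE and PAC are common in promoters of ribosome biogenesis genes, so these values are not independent of that list and may reflect it. The pattern was not particular to Q cells. In DS cells RRPE genes stood at 1.48 against 0.63 and PAC genes at 1.47 against 0.62. Xbp1 core genes stood at 0.77 against 0.61 there, and all 3 were at percentile 100. In log cells RRPE genes were lower than others, at 0.08 against 0.27 and percentile 0. The URS1 element of Ume6 (TAGCCGCC, 135 genes) went with 0.56 against 0.25 in log cells, at percentile 100. It also went with 0.91 against 0.64 in DS cells and 3.17 against 2.85 in Q cells, at percentiles 99.97 and 100. All 4 motifs were thus at percentile 100 in Q cells. No motif of an unrelated factor was tried for comparison, so these percentiles do not show that the pattern is particular to repressors that recruit Rpd3. No alternative processing was tried for the motifs.

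Another hypothesis was that genes near chromosome ends are lower in mutant log cells. The 10 outermost genes of each arm of 16 chromosomes (311 genes) had a median of -0.32 against 0.25 for all genes, at percentile 0 of random lists, with 76 at least 2-fold lower and 13 higher. In DS cells the median was -0.005 and in Q cells 2.01, against 0.64 and 2.81 for all genes, so these genes were higher than wild type in Q cells on the per-cell scale but below the median gene. Near-identical subtelomeric copies share reads, so single members are uncertain.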
